A study of Xerophyta schlechteri with 51 samples.

How the data were processed

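RNA was measured in leaf blades of Xerophyta schlechteri, a resurrection plant whose leaves survive near-complete drying and recover on rewatering. The series holds 51 libraries in 17 groups of 3. Each group is a stage of drying or recovery in a state of senescence. The stages were full turgor, 75%, 55%, 35% and <10% relative water content (RWC, the water held as a share of that at full turgor), and 48 h after rehydration. The states were non-senescent tissue (NST), pre-senescent tissue (PST) and senescent tissue (ST), and there was no PST group at full turgor. The label that gives the water content carries the NST abbreviation, so stages are given here as the water content of the NST. The labels' protocols state that water content varied after rehydration, and values per library were not used here. Groups were taken from the labels. Nothing in the labels says which samples came from separate plants, so p-values measure only the spread between these samples, which may be partly technical.

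The authors deposited 1 table of FPKM values (fragments per kilobase of transcript, scaled to the mapped fragments of the library), rounded to 2 decimals, with 1 column per library. Reads were processed with Bowtie2, TopHat and Cuffdiff, per the submitters' processing notes, and mapped to the reference genome of the species with the Tuxedo tools, per the series design text. Versions, settings, filters and the scaling used by Cuffdiff are not given in the sources used here. By definition FPKM divides by transcript length and by a library total. Median-ratio size factors of the deposited values lay between 1.01 and 1.04, so these were already scaled alike between libraries. A few abundant transcripts in 1 library therefore need not lower the others in it. The 10 highest entries held between 8.2% and 23.1% of the summed FPKM of a library.

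The table has 21815 entries with 21282 different gene IDs. A total of 499 IDs occur more than once and cover 1032 entries. These were kept as separate entries, and all entries are called genes below. The table pairs no ID with a gene name or annotation. The 29 gene lists fixed before the data were examined (among them late embryogenesis abundant proteins, photosystem proteins, senescence regulators and guard cell, phloem and xylem markers) matched 0 IDs, so the planned gene list tests were not run. The rule for named genes, written before the data were examined, called for members of those lists and for named or annotated genes with the largest changes. For a table without names it allowed IDs alone. These are the 2 IDs with the largest rise and the 2 with the largest fall in NST at <10% RWC against full turgor, among genes past the threshold whose libraries did not overlap and whose higher group had a mean of at least 10 FPKM.

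Counts of reads are not given by the table, so absolute depth is unknown. Because the lowest values of a gene are whole multiples of what 1 fragment is worth, that worth was compared between libraries over 5418 low genes. Relative depth here means the fragments behind 1 unit of FPKM, which includes the scaling of the values. Of the library pairs, 80.2% gave estimates that met within 0.05 on the log2 scale, and in simulated data the largest error was 0.011 on that scale over 12 libraries. Relative depth ran from 0.62 (rehydrated NST replicates 0 and 1) to 1.54 (ST at 55% RWC, replicate 0). Low genes are therefore less precise in rehydrated NST replicates 0 and 1. The dry groups share much of this. Mean relative depth was 0.743 in NST and 0.807 in ST at <10% RWC, against 1.25 and 1.29 at full turgor. These values need not follow the total fragments sequenced. The mean summed FPKM was higher at <10% RWC (866584 in NST, 980887 in ST) than at full turgor (568182 and 551001).

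Genes with an FPKM of at least 1 in at least 3 libraries were tested (18717 genes, with 3098 left out). Values were taken to log2(FPKM + 1), and fold changes are on that scale, which understates the change of low genes. limma 3.58.1 in R 4.3.3 fitted 1 mean per group over all 51 libraries, with a trend in the variance, giving 34 residual degrees of freedom. Tests were two-sided, with Benjamini-Hochberg adjustment within each comparison and a threshold of 0.05 on the adjusted p. This design, its 27 comparisons and most alternatives were fixed before the data were examined. Another 4 comparisons were added afterwards. These were the change from <10% RWC to rehydration in ST minus NST and in PST minus NST, and rehydrated ST against NST at 35% and at <10% RWC.

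The column names number the replicates of each group 0, 1 and 2, and these numbers name the libraries here. The labels themselves give no such numbers. Whether libraries of 1 number deviated together was checked by correlating deviations from the group means between tissues of 1 stage. A shared plant or a shared batch would both give this, and these were not told apart. In 14 of the 16 pairs of tissues every same-number correlation was over 0.1, with values from 0.38 to 0.87. The numbers were therefore taken to pair tissues of 1 stage. The main fit and the counts and set tests from it leave this pairing out. Pairing enters only where a block, pairs or exchanges within numbers are named. In the remaining 2 pairs, rehydrated NST with PST and with ST, the lowest same-number correlation was -0.06 and the highest 0.34, so those comparisons were not treated as paired. Between stages, every same-number correlation was over 0.1 in 3 of the 40 pairs of stages within a tissue. Among the comparisons made this covers ST at <10% RWC against full turgor, where the number as a block moved the count by less than 1.5 times. A fit with the replicate number within a stage as a block (22 residual degrees of freedom) is given beside a result where it moved a count by over 1.5 times.

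A position on the drying axis was computed for each library, as a description chosen after the data were examined. It is the projection of the log2 profile over all tested genes on the line from the mean of NST at full turgor (0) to the mean of NST at <10% RWC (1). Other axes were drawn from ST in the same way and from PST between 75% and <10% RWC. Sets of drying genes (adjusted p under 0.05 and a log2 change of at least 1) were followed through the groups, also chosen afterwards. They were tested with limma's camera at a preset correlation of 0.01 between genes and again with an estimated correlation, in 26 tests adjusted together. Each set came from libraries other than those compared. Such sets are taken from these data and are not independent annotations. Overlaps of lists are given beside the number that independent lists would share.

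The fit was tested on simulated data for NST at <10% RWC against full turgor, with 200 of 18717 genes changed. It recovered 17% of the genes changed by 1 on the log2 scale, 75% of those changed by 2 and 93.5% of those changed by 3, with 0, 9 and 9 false calls, and it called 0 genes in unchanged data. The adjusted threshold eases as more genes change, so these shares hold for that number of changed genes only. The simulated values were independent, with 1 SD per gene for all libraries. Weights estimated for the real libraries ran from 0.28 to 4.08, and false calls under such unequal spread were not tested. Alternatives were a pseudocount of 0.1, no filter, a filter of 5 FPKM, median-ratio size factors, a fold minimum, library weights, only the compared groups in the fit, the replicate block and leaving out each replicate in turn. Quantile normalization, leaving out repeated IDs and averaging rehydrated NST replicates 0 and 1 were added after the data were examined. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

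Genes lower in ST at full turgor were compared with 10000 random lists of genes that fell in dry NST. These were matched in bins of the level at full turgor, in bins of level and of the log2 fall, or by drawing for each gene 1 of its 50 nearest in both, each scaled by its SD. The last had a median fall of -2.37 against -2.40 for the list. The lists were drawn again without each full-turgor library of ST and NST.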

Results

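Transcript levels were measured by RNA sequencing in leaf blades of the resurrection plant Xerophyta schlechteri during drying and recovery. The series asked how tissue that senesces on drying differs from tissue that survives it. NST, PST and ST were sampled with 3 libraries per group. Between 13775 and 16157 genes reached an FPKM of at least 1 in a library. The fewest were found in rehydrated ST (14002 ± 245, SD, n = 3) and the most in ST and NST at full turgor (15989 ± 157 and 15980 ± 135, SD, n = 3 each). The summed FPKM ran from 551001 ± 50500 in ST at full turgor to 980887 ± 72500 in ST at <10% RWC (SD, n = 3 each), and absolute depth is unknown. Over all genes, the first principal component held 43.3% of the variance.

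The first question was how the NST transcriptome changed as leaves dried. Change was broad at the mildest stage and grew with water loss. At 75% RWC, 2023 genes were higher and 3027 lower than at full turgor. At 55% RWC the counts were 2910 and 4141, at 35% RWC 3912 and 5280, and at <10% RWC 4149 and 5543. At <10% RWC 51.8% of the tested genes had changed. The genes that rose by at least 1 on the log2 scale (3199 genes) had a median change of 0.83 ± 0.39 at 75% RWC, 1.24 ± 0.31 at 55%, 1.75 ± 0.21 at 35% and 1.89 ± 0.07 at <10% RWC (SD, n = 3 libraries each). The genes that fell by at least 1 (4466 genes) stood at -1.14 ± 0.28, -1.46 ± 0.19, -1.87 ± 0.07 and -1.96 ± 0.05 at the same stages. These sets were chosen on the <10% RWC libraries, which favours that stage. The balance of higher and lower genes depends on the scaling assumed. Quantile normalization moved the all-gene median log2 change by 0.12 at 75% RWC, 0.14 at 55%, 0.22 at 35% and 0.18 at <10% RWC. The higher share was then 52.3% in place of 42.6% at 35% RWC and 51.4% in place of 42.8% at <10% RWC. Quantile normalization gives every library the same distribution of values, so it evens out this balance by construction. Its shares, here and below, cannot tell a real imbalance from one of scaling.

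The genes with the largest changes in dry NST rose from low levels to among the most abundant transcripts, or fell from high levels to a listed 0. Xvis03_205230 rose from 5.50 ± 2.19 FPKM at full turgor to 28647 ± 6270 FPKM at <10% RWC (SD, n = 3 each), a log2 change of 12.14 with a standard error of 0.92 (limma, adjusted p = 4e-13). Xvis03_220597 stood between 3.34 and 10.88 FPKM in the 3 libraries at full turgor and rose to 28082 ± 10890 FPKM (SD, n = 3), with a log2 change of 12.01, a standard error of 0.98 and limma's adjusted p = 1.96e-12. Xvis03_218252 stood between 1086.97 and 1187.86 FPKM in the 3 NST libraries at full turgor and was listed at 0 in all 3 at <10% RWC (limma, adjusted p = 1.86e-07). Xvis03_222790 stood between 576.11 and 1341.03 FPKM at full turgor and was likewise listed at 0 in all 3 dry libraries (limma, adjusted p = 7.38e-12). An exact 0 in such a table can be a failed estimate, so no fold is given for these genes.

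The same comparisons in ST asked how senescing tissue responded to drying. At 75% RWC, 2813 genes were higher and 3721 lower than in ST at full turgor. The counts were 3153 and 4022 at 55% RWC, 3586 and 4812 at 35% RWC, and 4677 and 5493 at <10% RWC. In ST, the genes that rose in dry NST already stood 1.25 ± 0.29 above full turgor at 75% RWC and reached 1.79 ± 0.09 at <10% RWC (SD, n = 3 each). Xvis03_205230 stood at 38.1 ± 58.6 FPKM in ST at full turgor and at 20749 ± 9255 FPKM at <10% RWC. At 35% RWC, 42.7% of the called genes were higher, and 52.8% were after quantile normalization, which also turned the balance at 75% (50.1%), 55% (51.4%) and <10% RWC (50.4%).

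NST and ST shared most of the drying response. Of the 4149 genes higher in dry NST, 3056 were also higher in dry ST, against 1037 for independent lists, and 49 were lower. Of the 5543 genes lower in dry NST, 4151 were also lower in dry ST, against 1627, and 26 were higher. Across the 18717 genes, which are not independent replicates, the changes in the 2 tissues had a Pearson correlation of 0.869 and a Spearman correlation of 0.824, and 81.9% had the same sign. Deviations shared by libraries of 1 number accounted for a covariance of 0.116 out of 2.689.

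The difference between the tissues in their response to drying was tested directly. From full turgor to <10% RWC, 390 genes changed more upward in ST than in NST and 292 more downward. With the replicate number as a block the counts were 2222 and 1694. The direction of the balance depended on the setting. It was 254 upward and 329 downward with a pseudocount of 0.1, 213 and 337 with only the compared groups in the fit, 89 and 112 without ST at <10% RWC replicate 0, and 131 and 138 without NST at <10% RWC replicate 2. Leaving out 1 library moved the total of 682 by over 1.5 times for 6 of the 12 libraries. It was 201 without ST at <10% RWC replicate 0 and 1180 without replicate 1, 269 without NST at <10% RWC replicate 2, 324 without ST at full turgor replicate 1, and 448 and 364 without NST at full turgor replicates 0 and 2. For the named genes the change did not differ between the tissues past the threshold. The difference was -1.71 for Xvis03_205230 (limma, adjusted p = 0.57) and -2.92 for Xvis03_220597 (limma, adjusted p = 0.262). For Xvis03_218252 and Xvis03_222790 limma gave an adjusted p = 0.976 and an adjusted p = 0.992.

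**Figure D1:**
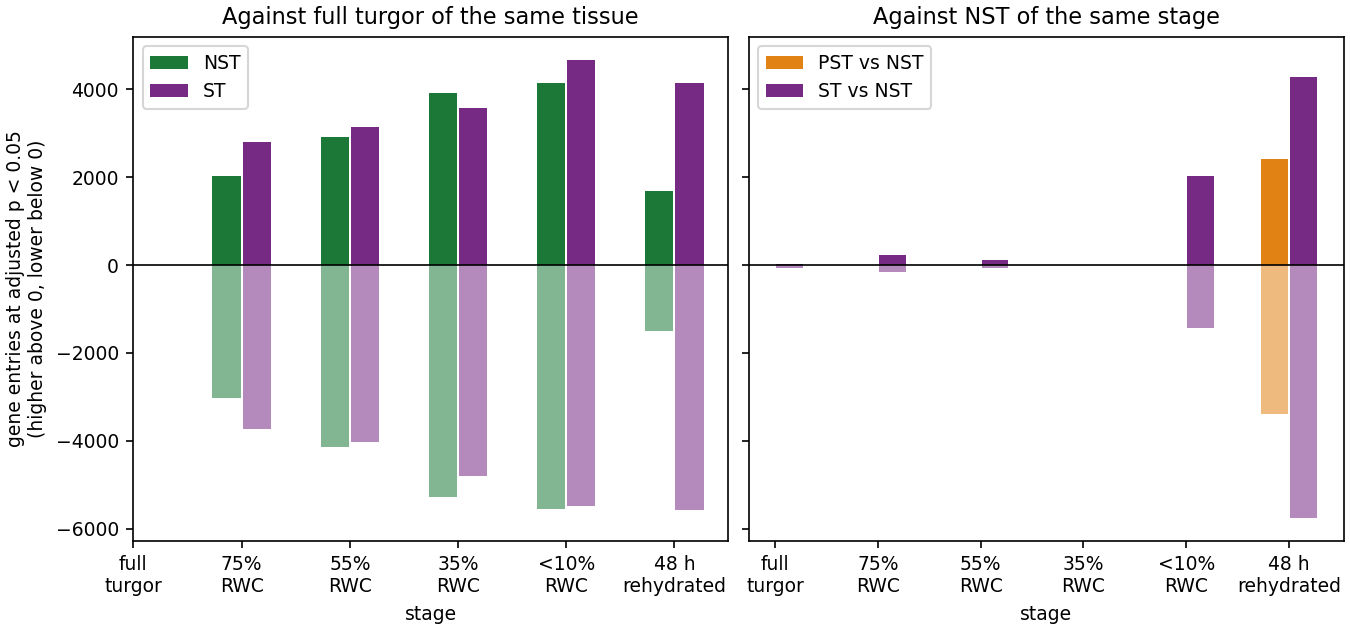
Number of genes past an adjusted p of 0.05 (vertical axis, higher genes above 0 and lower genes below 0) by stage, without the replicate block. The left panel compares NST and ST with full turgor of the same tissue, and the right panel compares PST and ST with NST of the same stage. In this fit ST against NST gave 383 genes at 75% RWC, 3473 at <10% RWC and 10048 after rehydration, while the block gave 4911 at 75% and 3712 at 55% RWC.

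ST was next compared with NST of the same stage, to ask when senescing tissue departs from surviving tissue. At full turgor 26 genes were higher and 57 lower in ST. The 57 lower genes were all among those that fell in drying NST, a comparison that shares the NST full-turgor libraries. With the block, 168 genes were higher and 174 lower at full turgor, and with only the compared groups in the fit the total was 2. A pseudocount of 0.1 gave 21 higher and 18 lower, and a filter of 5 FPKM 13 and 22, so neither the length of the lower list nor its excess held. The total of 83 fell to 19 without ST at full turgor replicate 0 and to 34 without NST at full turgor replicate 2. Of the 83 called genes, 31.3% were higher, and 41.7% were after quantile normalization.

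At 75% RWC the ST leaned from NST in the direction of further drying, which did not hold under every test. Stages are named by the water content of the NST, so ST at this stage may have held less water, which was not tested. There, 220 genes were higher and 163 lower in ST, and 2411 and 2500 with the block, but 4 in total with only the compared groups in the fit. The genes that rose in dry NST had a median difference of 0.42 between ST and NST at this stage, and those that fell had -0.36. By camera these sets had an adjusted p = 9.31e-16 and an adjusted p = 1.95e-13, but an adjusted p = 0.262 and an adjusted p = 0.216 with an estimated correlation. The total of 383 was 11 without ST at 75% RWC replicate 0, 714 without its replicate 1, and 42, 102 and 1446 without NST at 75% RWC replicates 0, 1 and 2.

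At 35% RWC the tissues lay closer, while 55% RWC was little below 75%. The root mean square log2 difference between ST and NST was 0.743 at 75%, 0.668 at 55% and 0.428 at 35% RWC. At 55% RWC 123 genes were higher and 66 lower in ST, and 1804 and 1908 with the block, but 0 in total with only the compared groups in the limma fit (2173 at an unadjusted p under 0.05). Quantile normalization moved the higher share from 65.1% to 76.1%. The total of 189 was 116, 6 and 881 without ST at 55% RWC replicates 0, 1 and 2, and 68, 78 and 9 without the NST replicates. At 35% RWC 2 genes were higher and 0 lower (limma), with 550 genes at an unadjusted p under 0.05. With the block, 141 were higher and 31 lower, with only the compared groups in the limma fit the total was 0 (768 at an unadjusted p under 0.05), and the unblocked total was 24 without ST at 35% RWC replicate 2 and 0 without any other of the 6 libraries.

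In the dry leaf ST differed from NST in many genes. At <10% RWC 2035 genes were higher and 1438 lower in ST than in NST, and 4002 and 3332 with the block, but 241 in total with only the compared groups in the fit. A group of 1643 genes stood at least 1 higher on the log2 scale. Relative to NST at full turgor, its median was 1.53 ± 0.62 in dry ST, -0.27 ± 0.28 in dry NST and 0.07 ± 0.16 in dry PST (SD, n = 3 libraries each). The 985 genes that were at least 1 lower stood at -1.01 ± 0.23 in dry ST and 0.52 ± 0.13 in dry NST. Both groups were chosen on these dry ST and NST libraries, so their gap between these tissues was fixed by the choice. The medians of the 1643 genes ran from 1.09 to 2.23 in dry ST. Of the 26 genes higher in ST at full turgor, 18 were also higher in dry ST, against 2.8 for independent lists. Without ST at full turgor replicate 0 this was 1 of 3 genes, and without NST at full turgor replicate 2 it was 3 of 7. ST at full turgor and at <10% RWC also shared deviations by replicate number (lowest correlation 0.17), so the lists are not independent. The total of 3473 fell to 1725 without ST at <10% RWC replicate 0 and to 1980 without NST at <10% RWC replicate 2, and the higher share of 58.6% was 47.9% after quantile normalization.

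PST could not be separated from NST by single genes at any drying stage, apart from 1 gene lower at 35% RWC. At 75%, 55% and <10% RWC limma called 0 genes, with 158, 303 and 354 genes at an unadjusted p under 0.05. The block gave 0 genes at 75% and at 55% RWC, 6 at 35% and 20 at <10% RWC. Leaving out 1 library gave 5 genes at 75% RWC without NST replicate 1, 2 at 35% without NST replicate 2, and 2 at <10% RWC without NST replicate 0, NST replicate 1 or PST replicate 2. As sets, the risen and fallen genes of dry NST differed between PST and NST at 55% RWC (camera, adjusted p = 0.000188 and adjusted p = 8.46e-05). With an estimated correlation camera gave an adjusted p = 0.866 and an adjusted p = 0.817. In dry leaves PST also differed from ST. There, 1155 genes were higher and 948 lower in ST than in PST, and 3186 and 2455 with the block, but 1 gene in total with only the compared groups in the fit. That total of 2103 fell to 729 without ST at <10% RWC replicate 0 and to 1142 without PST at <10% RWC replicate 2, and the higher share of 54.9% was 43.8% after quantile normalization.

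Rehydration separated the tissues. NST returned most of the way to its hydrated state, with 5740 genes higher and 4460 lower after 48 h than at <10% RWC, a higher share of 56.3% that was 48.5% after quantile normalization. The set that rose on drying stood at 0.09 ± 0.07 above full turgor in rehydrated NST and the set that fell at -0.14 ± 0.07 (SD, n = 3 each). Against full turgor, 1678 genes were higher and 1510 lower. Xvis03_205230 fell to 190 ± 111 FPKM in rehydrated NST, above its level at full turgor (log2 difference 4.77, standard error 0.92, limma adjusted p = 0.000275). The named fallen genes stayed below full turgor in rehydrated NST. Xvis03_222790 stood between 0 and 18.66 FPKM (limma, adjusted p = 2.18e-09) and Xvis03_218252 between 6.95 and 155.75 FPKM (limma, adjusted p = 0.00636). The total of 3188 against full turgor was 1879 and 1783 without rehydrated NST replicates 0 and 1, which resembled each other closely and had the lowest relative depth, and 2082 without NST at full turgor replicate 1. Library weights raised it to 7179 (3704 higher and 3475 lower). The balance turned with a pseudocount of 0.1 (1204 higher and 1353 lower) and with a filter of 5 FPKM (1211 and 1243).

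Rehydrated ST stayed near the dry state of NST. Against its own full turgor, 4136 genes were higher and 5585 lower. The genes that rose in dry NST stood 1.80 ± 0.08 above full turgor in rehydrated ST, and those that fell stood at -1.80 ± 0.12 (SD, n = 3 each). Of the 4149 genes higher in dry NST, 3305 (79.7%) were higher in rehydrated ST than at full turgor, against 917 for independent lists, and of the 5543 lower genes 4512 (81.4%) were lower, against 1654. In the reverse direction, 414 of the 4677 genes higher in dry ST were higher in rehydrated NST than at full turgor, where independent lists would share 419, and 876 of the 5493 genes lower in dry ST were lower there, where independent lists would share 443. The share of higher genes in rehydrated ST against full turgor was 42.5%, and 52.9% after quantile normalization, which moved the median of all genes by 0.25.

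Rehydrated ST was not simply unchanged dry ST. After rewatering, 2576 genes were higher and 3028 lower than in ST at <10% RWC. The group of 1643 genes that had marked dry ST had a median of 1.53 ± 0.62 in dry ST and of -0.45 ± 0.09 in rehydrated ST (SD, n = 3 each). It was chosen on the dry ST libraries, which favours the value there, and these ran from 1.09 to 2.23. Xvis03_205230 stood at 27833 ± 9588 FPKM in rehydrated ST against 20749 ± 9255 FPKM in dry ST, a difference short of the threshold (limma, adjusted p = 0.778). The total of 5604 was 3724 without ST at <10% RWC replicate 0 and 3047 with only the compared groups in the fit, and the higher share of 46% was 54.4% after quantile normalization. Rehydrated ST differed from NST at <10% RWC in 72 genes and from NST at 35% RWC in 13, comparisons chosen afterwards and made across stages. With only the compared groups in the limma fit they were 0 and 0, with 2472 and 1847 genes at an unadjusted p under 0.05. Leaving out any 1 of the libraries moved these totals by over 1.5 times. They were 179 and 117 without rehydrated ST replicate 2, 5 and 0 without its replicate 1, and 8 and 4 without its replicate 0. Without NST replicates 0, 1 and 2 the first was 24, 0 and 22 and the second 1, 0 and 0.

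PST took a middle course. In PST 3050 genes were higher and 2575 lower after rehydration than at <10% RWC, a total of 5625 that was 3297 and 3493 without rehydrated PST replicates 0 and 1, and 2146 with only the compared groups in the fit. The higher share of 54.2% was 50% after quantile normalization. The set that rose on drying stood at 1.02 ± 0.54 above NST at full turgor in rehydrated PST and the set that fell at -1.10 ± 0.44 (SD, n = 3 each). The 3 rehydrated PST libraries ranged widely, and Xvis03_205230 ran from 2027.34 to 17711.5 FPKM among them.

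**Figure D2:**
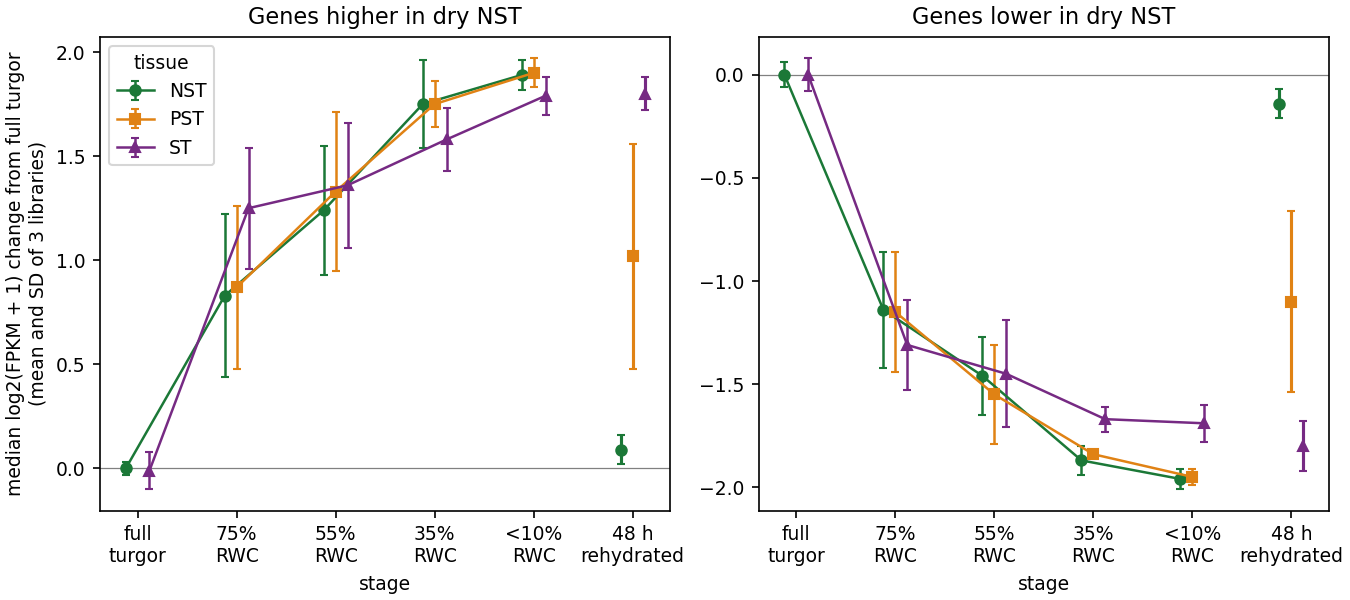
Median log2(FPKM + 1) change (vertical axis) of the 3199 genes that rose and the 4466 genes that fell in NST at <10% RWC, by stage and tissue. Points are means of 3 libraries and bars are SD. NST and PST are set against NST at full turgor, and ST against ST at full turgor. After rehydration the risen genes stood at 0.09 in NST, 1.02 in PST and 1.80 in ST.

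Compared directly after rehydration, ST had 4293 genes higher and 5755 lower than NST, and PST had 2424 higher and 3400 lower than NST. Quantile normalization turned this balance, from 42.7% higher to 51.4% for ST and from 41.6% to 50.1% for PST. Between ST and PST, 2043 genes were higher and 2271 lower in ST, and 4022 and 4316 with the block. This balance turned with quantile normalization (1583 higher and 1576 lower) and with a filter of 5 FPKM (2084 and 1983). With only the compared groups in the limma fit the ST against PST total was 0, with 5298 genes at an unadjusted p under 0.05, and the PST against NST total was 2989. The genes that had risen in dry NST were higher in rehydrated ST than in rehydrated NST by a median of 1.78 (camera, adjusted p = 6.53e-76, and adjusted p = 0.00311 with an estimated correlation). Those that had fallen were lower, with a median of -1.78 (camera, adjusted p = 1.33e-61, and adjusted p = 0.0028 with an estimated correlation). In PST against NST the medians were 0.91 and -0.91, each with an adjusted p = 0.0232 with an estimated correlation. In ST against PST they were 0.93 and -0.84, with an adjusted p = 0.0132 and an adjusted p = 0.00538 with an estimated correlation. The total for PST against NST was 3630 without rehydrated PST replicate 2. The total of 4314 for ST against PST was 2085 and 1773 without rehydrated PST replicates 0 and 1 and 2724 without rehydrated ST replicate 2.

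The recovery itself was also compared between the tissues, a test chosen afterwards. From <10% RWC to rehydration, 3959 genes changed more upward and 5565 more downward in ST than in NST. For PST against NST these counts were 948 and 1625. The total of 2573 for PST was 1555 without rehydrated PST replicate 2 and 1695 with only the compared groups in the fit. It was 4112 with library weights and 6598 with the block, although the numbers did not pair these samples. Quantile normalization moved the higher share from 41.6% to 52.5% for ST and from 36.8% to 48% for PST. Xvis03_205230 differed by 7.81 between ST and NST in this change (standard error 1.31, limma adjusted p = 6.93e-06).

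On the drying axis, where NST at full turgor lies at 0 and NST at <10% RWC at 1, the drying groups moved towards 1 in every tissue. At 75% RWC the position was 0.603 ± 0.153 in NST, 0.625 ± 0.159 in PST and 0.797 ± 0.104 in ST (SD, n = 3 each). After rehydration it was 0.0970 ± 0.0460 in NST, 0.545 ± 0.226 in PST and 0.945 ± 0.0620 in ST. All 3 rehydrated ST libraries lay between 0.888 and 1.011 and all 3 rehydrated NST libraries between 0.068 and 0.15. The difference of 0.848 had an exact permutation p = 0.1 (two-sided, n = 3 each), the smallest that 3 against 3 libraries allow. Whether ST lay ahead of NST depended on the stage, and the water content of ST itself was not used. ST lay further along than NST of the same number in 3 of 3 pairs at 75% RWC (mean 0.194 ± 0.156) and at 55% RWC (0.077 ± 0.019), and less far in 3 of 3 at 35% RWC (-0.022 ± 0.01) and at <10% RWC (-0.057 ± 0.058). Each stage had an exact sign-flip p = 0.25 (two-sided), the smallest that 3 pairs allow. Pooled over these opposite signs the difference was 0.048 ± 0.125 (SD over 12 pairs, exact sign-flip p = 0.2183, two-sided). On an axis drawn from PST the stages gave 0.426, 0.297, -0.03 and -0.124, and 0.142 ± 0.281 pooled (exact sign-flip p = 0.1016, two-sided). On an axis drawn from ST they gave 0.245, 0.131, 0.032 and 0.194, and 0.15 ± 0.111 pooled, higher in 11 of 12 pairs (exact sign-flip p = 0.001, two-sided). The NST and ST axes each fix the mean of a dry group that enters these pairs, so the pooled difference depends on the axis, while 75% and 55% RWC had the same sign on all 3. At full turgor ST already lay further along than NST by 0.079 ± 0.059 on the NST axis (3 of 3 pairs). The lead at 55% RWC on that axis was therefore no larger than before drying. On the ST and PST axes the difference at full turgor was 0.066 and -0.004, below that at 55% RWC. PST lay further along than NST in 10 of 12 pairs on the ST axis (mean 0.033 ± 0.039, exact sign-flip p = 0.0146, two-sided). On the NST and PST axes this was 8 and 7 of 12 (exact sign-flip p = 0.2275 and p = 0.1104, two-sided).

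**Figure D3:**
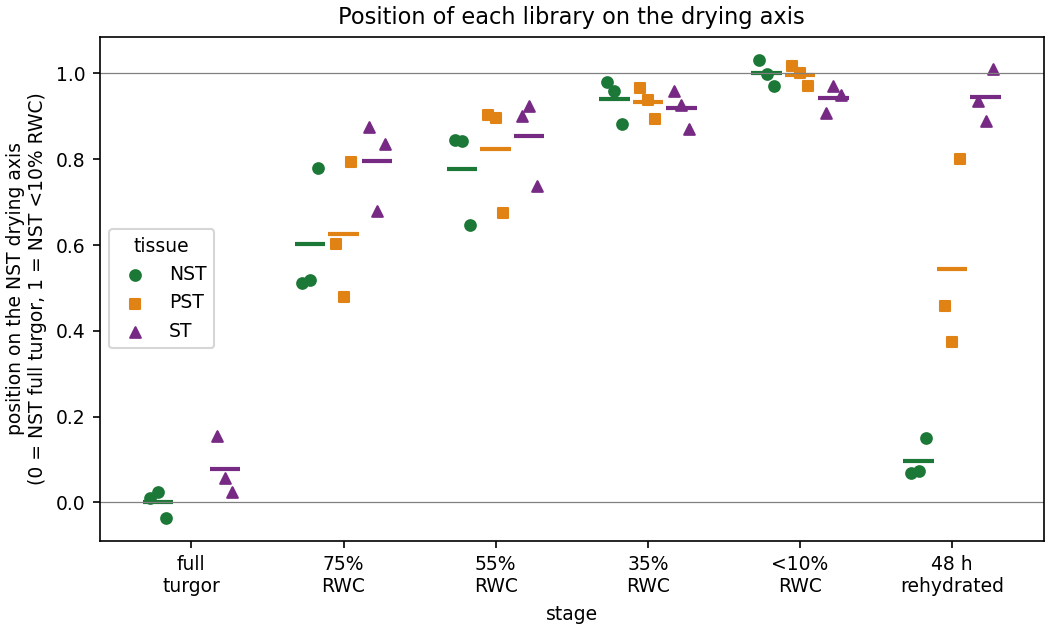
Position of each library on the drying axis (vertical axis, without unit, 0 for the mean of NST at full turgor and 1 for the mean of NST at <10% RWC) by stage. Points are libraries and lines are means of 3 libraries. After 48 h of rehydration NST lay at 0.0970, PST at 0.545 and ST at 0.945.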

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

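The comparisons of recovery between tissues and all tests of explanations given here were chosen, and their bounds set, after the results were seen.

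The drying response differed between ST and NST in 682 genes. Of the 32 exchanges of tissue labels within replicate numbers, 6 gave as many genes, and the highest other gave 1706, but these exchanges cannot decide. Of the 32, 8 leave the labels in dry leaves as they are or exchange them all, which keeps the difference in dry leaves, and all 6 were among them. In the other 24 the highest count was 11. With the replicate number as a block the real count was 3916.

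The recovery from <10% RWC to rehydration differed between ST and NST in 9524 genes (3959 more upward, 5565 more downward in ST). In 100 drawn splits only the real one, 1 of 100, gave as many, and the highest other gave 8282. Of the 100, 9 keep the difference in rehydrated leaves, too few for a share under 0.05 among them, and in the other 91 the highest count was 2956, so this cannot decide either. Between PST and NST the recovery differed in 2573 genes (948 and 1625). There 6 of 100 splits gave as many, the highest other 3650. All 6 were among the 8 splits that keep the difference in rehydrated leaves, so this share cannot decide, and in the other 92 the highest count was 219.

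Other counts came from 3 against 3 libraries, which make 10 splits, too few for a share under 0.05. In NST against full turgor 1 of 10 splits, the real one, gave as many genes at each drying stage (real 5050, 7051, 9192 and 9692, highest other 14, 6, 3 and 1). The same held in ST (6534, 7175, 8398 and 10170, highest other 2, 2, 1 and 54). For rehydration against <10% RWC the real and highest other counts were 10200 and 307 in NST, 5625 and 1208 in PST, and 5604 and 51 in ST. Against full turgor they were 3188 and 517 in NST and 9721 and 2 in ST.

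For ST against NST the real and highest other counts were 83 and 63 at full turgor, 383 and 368 at 75% RWC, 189 and 150 at 55%, 3473 and 245 at <10% and 10048 and 1052 after rehydration. At 35% RWC 2 of 10 splits gave the real count of 2. For PST against NST all 10 splits reached the count of 0 at 75%, 55% and <10% RWC, and the highest other was 776, 1 and 1. At 35% RWC the real count was 1 and the highest other 0, and after rehydration 5824 and 1163. The 776 genes at 75% RWC came from a split that did not part the replicate numbers evenly, so differences between numbers entered it. Whether these lie between plants or batches was not tested. ST against PST gave 2103 with a highest other of 279 at <10% RWC, and 4314 with 2370 after rehydration. Of the 4 splits that put 1 tissue of each replicate number on each side, the highest other gave 4 genes for ST against NST at <10% RWC, 1 gene for PST against NST at <10% RWC and 0 in every other paired comparison. Rehydrated ST against NST at 35% and at <10% RWC gave 13 and 72, with 7 and 33 as the highest others.

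The first pattern weighed was that all 3 rehydrated ST libraries lay at the dry end of the drying axis. An exchange of the labels of dry and rehydrated ST would leave this pattern in place, because dry ST had a mean position of 0.943. The same-number correlations of rehydrated ST with rehydrated PST, at least 0.38, argue against such an exchange but do not bear on the position. Depth is argued against by the 1187 genes with a mean of at least 100 FPKM, on which the lowest rehydrated ST library lay at 0.88, and scaling between libraries by ranks within a library, on which the lowest lay at 0.88 and the highest rehydrated NST library at 0.18. That rehydrated ST stayed far from the hydrated profile may be biological, as a hypothesis, although ST did change from its own dry profile (5604 genes). On the axis drawn from ST, the rehydrated ST libraries lay between 0.686 and 0.797, part of the way back from the dry ST mean at 1. That axis was drawn through the dry ST libraries, which favours this distance. The water content of these samples stays open as an untested explanation.

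The second pattern was that rehydrated ST lay closer to dry NST (72 genes) than to dry ST (5604 genes). A single dry ST library set apart from the others is argued against as the whole cause, because leaving out each in turn left at least 3724 genes. Depth is argued against, because among genes with a mean of at least 100 FPKM 33.2% were called against dry ST and 0.2% against dry NST. A possible explanation is that rehydrated ST lost the transcripts particular to dry ST without returning to the hydrated state. Quantile normalization gave 5 genes against dry NST and 5110 against dry ST, and the water content of the rehydrated samples stays open as an untested explanation.

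The third pattern was that rehydrated NST replicates 0 and 1 were nearly alike, with a spread of 0.232 between them against 0.369 to 0.991 for the 50 other pairs of 1 group. Some libraries of different groups were about as close. NST and PST at 75% RWC replicate 1 had 0.209, NST and ST at full turgor replicate 2 had 0.233, and NST at 35% RWC replicate 0 and NST at <10% RWC replicate 1 had 0.234. A shared source numbered 0, such as 1 plant, stays open for both NST replicates. The correlation of NST replicate 1 with PST replicate 0 (0.33) cannot decide, because it restates their likeness, NST replicate 0 having 0.34. A column deposited more than once is argued against, because 0.09% of the genes with a mean of at least 10 FPKM in the pair had identical values. A library sequenced more than once was weighed by the chi-square of recovered fragment counts, whose median was 1.64 against 0.455 for sampling alone. As 2 pairs of other groups were lower still, this cannot be told apart from very similar samples, and the libraries were kept as 2. No biological explanation was tested.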

How the results depend on the processing

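Quantile normalization, leaving out repeated IDs, averaging rehydrated NST replicates 0 and 1, all alternatives for positions, the matched lists for the genes of ST at full turgor and all 4 added comparisons were chosen after seeing the data. Counts stayed within 1.5 times of the reported count in 31 of 31 comparisons under median-ratio size factors (a void test, as the values were already scaled alike), a fold minimum and leaving out repeated IDs. The planned gene list tests, fry included, were not run because no list matched an ID. The cause of the moves below was not tested, except where fewer samples or genes entered by construction. Depth is known only between libraries, so a limit of detection per gene cannot be given.

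A pseudocount of 0.1 gave 39 genes for ST against NST at full turgor, 5 at 35% RWC and 27 for rehydrated ST against NST at 35% RWC. With no filter ST against NST gave 131 at full turgor and 1 at 35% RWC, and PST against NST gave 4 at <10% RWC. A filter of 5 gave 35 for ST against NST at full turgor. Quantile normalization gave 113 for ST against NST at 55% RWC, 1 for PST against NST at <10% RWC, and 2 and 5 for rehydrated ST against NST at 35% and <10% RWC.

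With only the compared groups in the fit, which leaves fewer samples to estimate the spread, 13 counts were lower. ST against NST gave 2 at full turgor, 4 at 75%, 0 at 55%, 0 at 35% and 241 at <10% RWC, ST against PST gave 1 at <10% RWC and 0 after rehydration, and PST against NST gave 2989 after rehydration. Rehydration against <10% RWC gave 2146 in PST and 3047 in ST. The recovery of PST minus NST gave 1695, and rehydrated ST against NST at 35% and <10% RWC gave 0 and 0.

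Library weights raised 13 counts. NST gave 7637 at 75% RWC and 7179 after rehydration, both against full turgor. ST against NST gave 212 at full turgor, 4128 at 75%, 812 at 55% and 320 at 35% RWC, PST against NST gave 6 at 35% and 3 at <10% RWC, and ST against PST gave 6694 after rehydration. The drying difference of ST minus NST gave 1259 and the recovery of PST minus NST 4112. Rehydrated ST against NST at 35% and <10% RWC gave 228 and 418.

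The replicate number within a stage as a block raised 12 of 16 counts. ST against NST gave 342 at full turgor, 4911 at 75%, 3712 at 55%, 172 at 35% and 7334 at <10% RWC, PST against NST gave 6 at 35% and 20 at <10% RWC, ST against PST gave 5641 at <10% RWC and 8338 after rehydration, and the drying difference gave 3916. In the comparisons where numbers did not pair the samples, the block gave 9587 for rehydrated PST against NST and 6598 for the recovery of PST minus NST. In rehydrated NST with PST or ST, 2 of 3 libraries correlated best with their own number. Across stages, the number as a block gave 35 and 122 for rehydrated ST against NST at 35% and <10% RWC. Among the set tests the block changed 1 call, that of the fallen genes in ST against NST at 35% RWC (camera, adjusted p = 0.0584 without and adjusted p = 0.0397 with the block, and adjusted p = 0.802 with the block and an estimated correlation).

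Rehydrated NST against full turgor gave 1774 with replicates 0 and 1 averaged. On an axis drawn from ST, rehydrated NST lay at 0.027 and rehydrated ST at 0.732, so the order of the tissues was the same. Rehydrated ST there lay short of the dry ST mean, which is 1 on that axis.

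Leaving out 1 library in turn moved these counts by over 1.5 times, with ranges as follows. ST against NST ranged from 19 to 94 at full turgor, 11 to 1446 at 75%, 6 to 881 at 55%, 0 to 24 at 35% and 1725 to 3547 at <10% RWC. PST against NST ranged from 0 to 5 at 75%, 1 to 2 at 35%, 0 to 2 at <10% RWC and 3630 to 5798 after rehydration. ST against PST ranged from 729 to 2510 at <10% RWC and 1773 to 5848 after rehydration. Rehydration against <10% RWC ranged from 3297 to 6812 in PST and 3724 to 5399 in ST, and against full turgor from 1783 to 3701 in NST. The drying difference ranged from 201 to 1180 and the recovery of PST minus NST from 1555 to 2936. Rehydrated ST against NST ranged from 0 to 117 at 35% and 0 to 179 at <10% RWC.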

Other observations

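The comparisons, correlations and the test given here were chosen after the data were examined.

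The 1643 genes that were at least 1 higher on the log2 scale in dry ST than in dry NST lay higher in ST than in NST in the mean at every drying stage. Relative to NST at full turgor their median was 0.19 ± 0.18 in ST at full turgor, 0.55 ± 0.47 at 75% RWC, 0.47 ± 0.37 at 55%, 0.03 ± 0.26 at 35%, 1.53 ± 0.62 at <10% RWC and -0.45 ± 0.09 after rehydration (SD, n = 3 libraries each). At the same 4 drying stages the means were -0.01, -0.07, -0.46 and -0.27 in NST and 0.19, -0.06, -0.28 and 0.07 in PST, so a low point at 35% RWC was not particular to ST. After rehydration they were -0.05 in NST and -0.21 in PST. These genes were chosen on the dry libraries, so their values there are favoured. Correlations between group means across genes, which are not independent replicates, placed rehydrated ST nearest to NST at 35% RWC (0.971), PST at 35% RWC (0.97) and NST at <10% RWC (0.968).

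The genes that were lower in ST at full turgor overlapped with those lower after rehydration, but the overlap could not be set apart from their strong fall on drying. Of these 57 genes, 49 were lower in rehydrated PST than in rehydrated NST and 53 in rehydrated ST. They had fallen by a median of -2.40 in dry NST, against -1.66 for all fallen genes. In 10000 random lists of drying-fallen genes with like levels at full turgor, a median of 24 and at most 39 were lower in rehydrated PST (share 1e-04, the smallest these lists can give).

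Lists matched in bins on level and on the size of the fall had a median of 28, and lists of the nearest genes in both had 32 (share 1e-04). The list itself fell to 16 genes without ST at full turgor replicate 0 and to 27 without NST at full turgor replicate 2. With the nearest genes the PST shares were then 0.0267 and 0.0756, and with bins 0.0053 and 0.0179. For rehydrated ST the nearest genes had a median of 47 against the 53, a share of 0.0114, and shares of 0.612 and 0.861 without those libraries. Whether the overlap exceeds that of other strongly falling genes therefore stays open.

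Between stages, every same-number correlation of deviations was over 0.1 and above every other in NST at 55% with <10% RWC (lowest 0.28, highest other -0.04), PST at 55% with <10% RWC (0.11 and 0.07) and ST at full turgor with <10% RWC (0.17 and 0.05). They were above every other but not over 0.1 in NST at full turgor with <10% RWC (0.05 and 0.01) and ST at 55% with <10% RWC (0.08 and 0.03). Elsewhere libraries with different numbers sometimes matched best. NST at 35% RWC replicate 0 and NST at <10% RWC replicate 1 had a correlation of deviations of 0.55, and NST at 55% RWC replicate 1 and NST at 35% RWC replicate 0 had 0.5.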
